A study of Homo sapiens with 92 samples.

How the data were processed

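ChIP-seq peak lists of 69 libraries were analysed, 1 list per library, and 23 control libraries of unprecipitated chromatin (10 in HepG2, 6 in GM12878, 6 in K562 and 1 in MCF7) entered only through the lists that were called against them. Per the labels' protocols, cells were fixed with 1% formaldehyde, chromatin was sheared by sonication, and 5 micrograms of antibody on magnetic beads were used in each reaction. The series design calls the repeats biological replicates. The labels give them no numbers. Permutation p-values rest only on the spread between these libraries or their groups. Those of Fisher's exact tests count regions or peaks of single lists and hold no spread between libraries, and those of sign tests count clones. Bowtie2, MACS2 and build hg19 are named in the submitters' processing notes, with no versions. Parameters were not given in the sources used here. The files are MACS2 narrowPeak lists, 1 per library, so peaks were not called on pooled replicates.

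The deposited lists give for each peak its position and summit, a fold enrichment over the control (a linear ratio), a p-value and a q-value as −log10, and a score that is the integer part of 10 times the −log10 q-value; all are the authors' values. The lowest deposited −log10 q over all lists was about 1.3, a q-value of 0.05, and the lowest within a list was up to 1.76. Fold enrichment and −log10 p were used only to rank peaks within a list and to describe the regions named below. Fold enrichments of different lists are printed side by side there, but their differences were not tested. Neither read counts nor depths are in the lists, so depth was unknown, and the number of peaks moves with depth, antibody and control together. Wilson 95% intervals of overlap percentages cover counting error over peaks only. For lists of at least 500 peaks they spanned at most 3.27 percentage points on either side. No 2 lists were identical, and at most 0.0526% of the intervals of a list were in another list with the same start and end.

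Groups were formed from target, clone and cell line in the labels. Overlap meant at least 1 shared base pair. The similarity of a pair of libraries was the percentage of the 500 peaks with the lowest p-values in one list that overlapped any of the 500 in the other, averaged over both directions, with shorter lists used whole. Mean similarity was compared between kinds of pairs with two-sided permutation tests, shuffling the labels within each cell line 100000 times. The same test was applied to the absolute difference of log10 peak number. For the test of shared controls the control assignments were shuffled. The control was taken from the descriptions of the control libraries, which name a control of the same line for 61 lists. The other 8 lists, among them both KLF10 lists and that of ZBTB2 in GM12878, were left out of that test. In those descriptions 4 lists are named under a control of another line, 3 of them also under a control of their own line, and 4 further names belong to libraries not analysed here.

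Peaks of a line were merged into regions, and pairs of one target, as well as BATF with BATF3, HMG20A with ZMYM3, RUVBL1 with ZMYM3 and L3MBTL4 with TSC22D4, were compared over these with Fisher's exact test and Benjamini-Hochberg adjustment over 45 pairs. Odds ratios had 0.5 added to each count. Regions called for at least 50% of the targets of a line were called recurrent. Regions to name were chosen by a rule fixed before the data were examined. For a target with several libraries in a line the rule takes up to 10 non-recurrent regions called in every library, ordered by mean rank of −log10 p. For a target with 1 library it takes 3, and for a clone in several lines 3 that are called in every library of the clone. The text prints the first 1 to 3 regions of some of these lists, and which lists to print was chosen with the values in view; results hold all of them. All target pairs outside this list, such as DPF1 with USF2, and the rule that lists opposite changes of peak number were chosen after values were seen. So were some tests of explanations. For chromosome 20 the predictions written beforehand compared HepG2 with the other lines. When 7 of 9 clones were seen to be higher in HepG2, which decided nothing, HepG2 and MCF7 were set together against GM12878 and K562. Both are given, and only the first counts as a test. The permutation test for its difference of means was specified after the shares had been seen. The pattern of BATF in ZBTB2 lists was widened to DRAP1 after its overlap was seen. The test of the HepG2 ZBTB2 library alone was added after the wider test of carry-over had come out as carry-over predicts. It was first read as excluding that library, and this was withdrawn, with its prediction reworded, because the strongest peaks point the other way for BATF.

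The alternatives were the 1000 strongest peaks, all peaks, ranking by fold enrichment, reciprocal overlap of 50%, a −log10 q of at least 5, removal of recurrent regions, removal of pairs with a shared control, and leaving out single libraries. On simulated lists drawn from 126424 HepG2 regions, in which replicates shared 60% of 500 sites, the similarity test gave a mean of 60.1% for replicates and 0.382% for others. With no sharing the test gave p = 0.907 in the same permutation test. The simulated lists were alike in length, held no recurrent regions and had no library in more than 1 pair of replicates. How the test behaves with these features of the real lists was therefore not simulated. A planted odds ratio of 23.2 came out as 23.3. Overlap counts were checked against bedtools. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. Planned tests of distance to transcription starts, of recognition motifs at summits, and of gene lists and cell type markers needed a genome or annotation of build hg19 and were not run. The gene table at hand is on another build, GRCh38.p14, and none of its coordinates were used.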

Results

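Monoclonal antibodies against 35 human transcription factors and chromatin proteins were tried in chromatin immunoprecipitation followed by sequencing (ChIP-seq), in which DNA crosslinked to a protein is pulled down with an antibody against it and sequenced. The 69 libraries with a peak list came from 45 antibody clones in 4 established human cell lines. GM12878, a B-lymphoblastoid line, had 17 libraries against 13 targets, and HepG2, a liver cancer line, had 25 libraries against 17 targets. K562, a chronic myeloid leukaemia line, had 16 libraries against 11 targets, and MCF7, a breast cancer line, had 11 libraries against 9 targets. A group was a target, clone and cell line. Of the 60 groups, 7 had 2 libraries, 1 had 3 libraries, and the others had 1 library each. The comparisons below ask how alike the peak lists were for repeats of one clone, for different clones against one target, for one clone in different lines, and for different targets. Positions are on build hg19, and fold enrichment is the authors' own value for each peak. No replicate error exists for groups with 1 library, and read depth was unknown because the peak lists hold no counts.

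The lists held 690107 peaks in all. ZBTB2, a BTB zinc finger protein, had the longest lists, with 51960 peaks in GM12878 and 47730 in HepG2. The next longest was that of USF2, a basic helix-loop-helix factor that binds E-boxes, in GM12878, with 35390 peaks. ZMYM3, a zinc finger protein of histone demethylase and deacetylase complexes, had 29795 and 24390 peaks in the 2 K562 libraries of clone JH39.2.2F10. The next in length among the others were those of ETV6 R1092.1.1A9 (26505), NFIA in K562 (25402), NFATC3 (24375), ZXDC (22866), USF2 in HepG2 (21847) and NRF1 R157.1.3D4 in K562 (20389). The shortest lists were 67 peaks for replicate 1 of HMG20A in GM12878, 757 for ATF2 in HepG2, 1296 for ZSCAN2 in HepG2 and 1445 for the p53 relative TP73 in GM12878. The median was 6618 peaks over the 69 lists. By line it was 9881 in GM12878, 8094 in HepG2, 7223 in K562 and 4427 in MCF7.

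**Figure D1:**
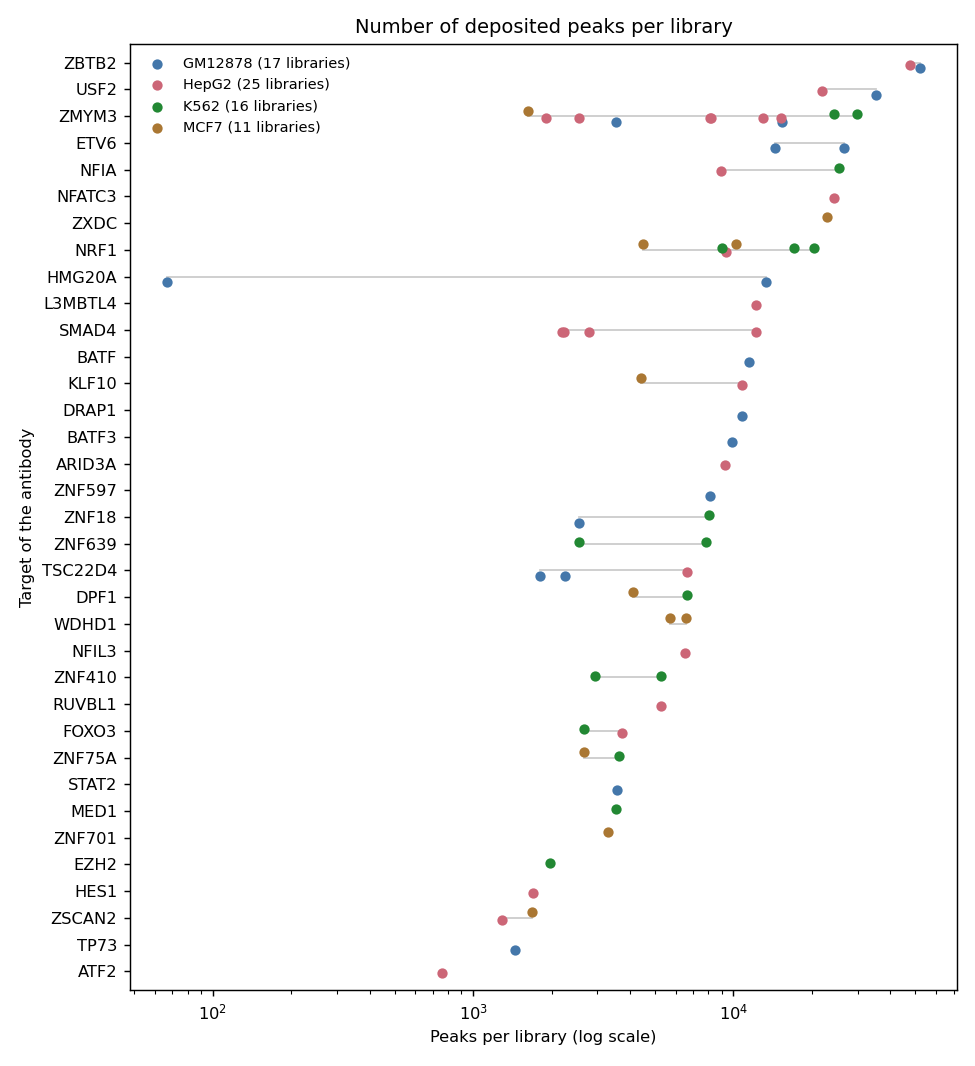
Each point is one library, placed by its number of deposited peaks (horizontal log axis) and its target (vertical axis), and coloured by cell line; grey lines join the shortest and longest list of a target. The lists run from 67 peaks for one HMG20A library to 51960 for ZBTB2 in GM12878.

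Whether repeats of one clone in one line had more similar numbers of peaks than antibodies against different targets was not settled. HMG20A differed most, with 67 and 13312 peaks, a ratio of 199. The 3 HepG2 libraries of ZMYM3 JH39.2.2F10 held 13000, 2559 and 15260 peaks (mean 10273 ± 6775 SD, n = 3), and the 2 GM12878 libraries of the same clone held 3542 and 15414. ZMYM3 JH39.2.2B9 in HepG2 was closest, with 8219 and 8094 peaks (mean 8157 ± 88.4 SD, n = 2). Over the 10 pairs of repeats the absolute difference of log10 peak number averaged 0.504, against 0.544 over the 578 pairs of different targets in one line. The difference of -0.041 was not past the threshold in a two-sided permutation test (p = 0.653). It depended on HMG20A: without its replicate 1 it was -0.200 (permutation test, p = 0.0787) and without its replicate 2 -0.244 (permutation test, p = 0.0555), while leaving out other libraries gave values up to 0.0108.

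Which sites were strongest, in contrast, was shared between repeats. Similarity below is the percentage of the 500 strongest peaks of one list, ranked by p-value, that overlapped any of the 500 strongest of the other, averaged over both directions. It averaged 53.9% ± 14.2 (SD over 10 pairs) for repeats of one clone in one line and 4.22% ± 6.40 (SD over 578 pairs) for different targets in one line. The difference of 49.7 percentage points gave p = 2e-05 in a two-sided permutation test, the smallest that 100000 permutations can give. Of the 10 pairs of repeats, 4 were of ZMYM3 in HepG2, and pairs that share a library are not independent. ZMYM3 JH39.2.2F10 repeats reached 68.2% in K562, 57.9% in GM12878 and 52.1 to 70.0% in HepG2, and JH39.2.2B9 repeats reached 65.4% in HepG2. SMAD4, the shared mediator of TGF-beta and BMP signalling, reached 57.1% with clone R516.2.1D12 in HepG2. TSC22D4 reached 48.5% in GM12878 and the zinc finger protein ZNF410 reached 45.0% in K562. Each of these values lay above every pair of different targets in its line.

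HMG20A, an HMG-box protein of the CoREST complex, was the exception at 21%. Of the 67 peaks of its replicate 1, 71.6% overlapped the 13312 peaks of replicate 2, but 86.6% of them lay in recurrent regions, defined here as regions called for at least 50% of the targets of a line. In replicate 2 that share was 6.23%. Replicate 1 also had 23 peaks on the mitochondrial chromosome and peaks as narrow as 52 bp, whereas the narrowest peak of replicate 2 was 170 bp. The 2 lists shared 31 regions, of which 6 were not recurrent. The first of these by rank lay at chromosome 1, 1624207 to 1624756, with fold enrichments of 10 and 47.5, and the second at chromosome 19, 6737139 to 6737686, with 7.5 and 25.7.

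**Figure D2:**
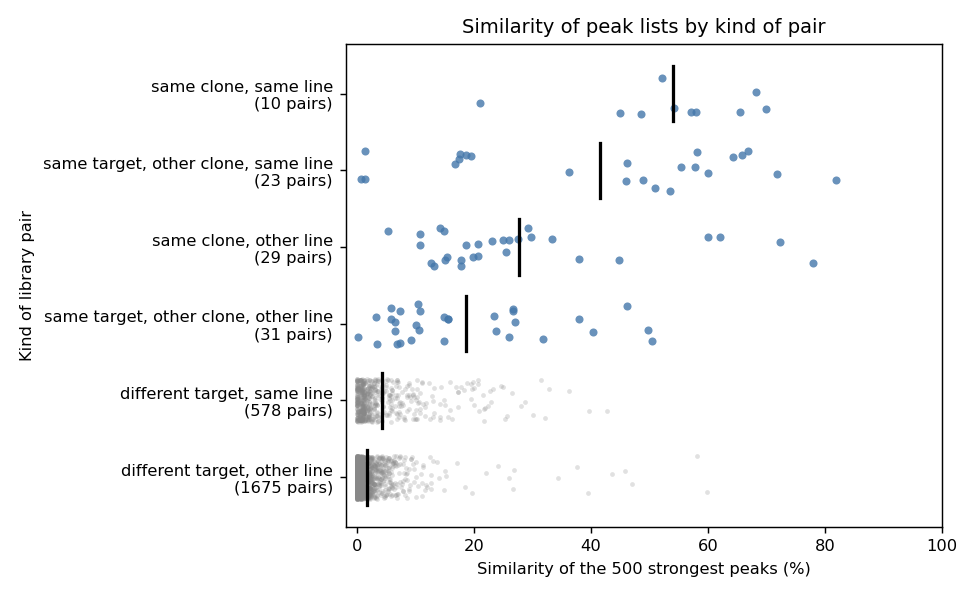
Each point is a pair of libraries, placed by the similarity of their 500 strongest peaks in percent (horizontal axis) and by the kind of pair (vertical axis, with jitter); black bars are means. Repeats of one clone in one line average 53.9%, different clones against one target in one line 41.6%, and different targets in one line 4.22%.

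For ZMYM3, the non-recurrent regions called in every library of a line were ordered by mean rank of −log10 p. In K562 the first 3 were chromosome 1, 205719586 to 205720419 (fold enrichment 34.2 to 62.4), chromosome 19, 54605584 to 54606521 (33.2 to 59.2) and chromosome 19, 14116008 to 14116651 (39.0 to 63.4). In GM12878 they were chromosome 22, 35524162 to 35525352 (25.4 to 52.1), chromosome 9, 71650104 to 71650838 (31.2 to 33.3) and chromosome 7, 5436646 to 5437494 (30.9 to 32.2). In HepG2, 6 libraries of 3 clones shared 257 regions, the first at chromosome 19, 4870011 to 4870613 (7.71 to 30.3). Without the R259.2.2C3 library the count was 1419. For ZNF410 in K562, 2231 regions were in both lists, led by chromosome 13, 113951072 to 113951664 (30 to 40.6), chromosome 15, 72667990 to 72668703 (22.5 to 51) and chromosome 16, 1401782 to 1402133 (31.4 to 31.9). For TSC22D4 in GM12878, 900 regions were in both lists, led by chromosome 9, 20640352 to 20641149 (22.3 to 34.8).

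Different clones against one target shared their strongest sites for most targets and not for others. ETV6, a transcriptional repressor of the ETS family, gave the highest value, 81.9% between clones R1092.1.1A7 and R1092.1.1A9 in GM12878, with 91.4% of the shorter list (Wilson 95% interval 90.9 to 91.8%) inside the longer. NRF1, an activator of nuclear genes for mitochondrial function, was tried with 3 clones in K562. Clones R157.1.3D4 and R157.1.3H3 reached 71.8%, and R157.1.3H1 reached 36.2 and 46.2% with them, although 99.2% and 98.6% of its peaks lay in the lists of R157.1.3D4 and R157.1.3H3. In MCF7, R157.1.3D4 and R157.1.3H1 reached 55.4%. The 2 WDHD1 clones in MCF7 reached 50.9% and the 2 ZNF639 clones in K562 46.0%. ZMYM3 clones JH39.2.2F10 and JH39.2.2B9 reached 48.8 to 66.8% in HepG2 over 6 pairs of libraries.

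Another ZMYM3 clone and another SMAD4 clone gave lower values. Their clone numbers differ in the first part from those they are compared with, whereas the clones of each pair above share it. Whether clones with a shared first part were derived independently was not examined. ZMYM3 R259.2.2C3 reached 16.8 to 19.5% with the 5 JH39 libraries in HepG2. These values lay at the 92.47th to 94.98th percentile of different-target pairs of that line, below the highest of them (32.8%). The R259.2.2C3 list held 1901 peaks, and 29.2% of its strongest were in recurrent regions, against 7.8 to 11.2% for the JH39 libraries. R259.2.2C3 reached 28% with FOXO3 in HepG2. SMAD4 R516.1.1G12 reached 58.1 and 65.8% with the R516.2.1D12 libraries, whereas SMAD4 13.2.1A5 reached 0.6 to 1.4% with the 3 R516 libraries, below the different-target median of 2.20%. The 3 R516 libraries shared 1281 regions, and the 4 SMAD4 libraries 44. The highest fold enrichment in the 13.2.1A5 list was 10.2, against 28.1 to 45.8 in the R516 lists. Whether such differences between lists or the clones themselves give the lower values was not tested. Over the 23 pairs of different clones the mean similarity was 41.6% ± 24.7 (SD), 37.4 percentage points above different targets (two-sided permutation test, p = 2e-05, the smallest possible). Of these pairs, 11 were of ZMYM3 and 5 of SMAD4, both in HepG2, and pairs that share a library are not independent.

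The first-ranked regions shared by clones ranged widely in fold enrichment. For ETV6 in GM12878, 12865 regions were in both lists, led by chromosome 10, 104153566 to 104155512 (fold enrichment 96.3 to 109), chromosome 20, 44739567 to 44741017 (78.9 to 87.3) and chromosome 5, 43039522 to 43041297 (76.0 to 77.5). For NRF1, 8393 regions were in all 3 K562 lists (15195 without R157.1.3H1), led by chromosome 13, 77900958 to 77901519 (61.7 to 89.5) and chromosome 16, 27560974 to 27561612 (58.6 to 87.8). In MCF7 4318 regions were in both NRF1 lists, led by chromosome 5, 218017 to 218517 (84.4 to 154.0). WDHD1, a replication-associated protein, had lower values in MCF7, with 15.1 to 16.2 at its first region, chromosome 17, 31149517 to 31149964. SMAD4 in HepG2 had 4.87 to 12.8 at its first region, chromosome 8, 145051187 to 145051686. ZNF639 in K562 had 24.5 to 37.1 at chromosome 11, 66189104 to 66189418.

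The pairs of libraries of one target were also tested over all merged regions of their line with Fisher's exact test and Benjamini-Hochberg adjustment over 45 pairs. These tests compare lists, not conditions, and neighbouring regions are not independent. Independent lists here are lists drawn independently from the regions called in that line, not from the genome. All 33 pairs overlapped more than independent lists would, with odds ratios from 1.52 (SMAD4 13.2.1A5 with R516.2.1D12 replicate 2, adjusted p = 0.00464) to 891. The lowest of these did not hold in 3 alternatives. Its odds ratio was 1.00 among peaks with a −log10 q of at least 5 and 0.899 without recurrent regions. Under reciprocal overlap of 50% it was 0.436 (Fisher's exact test, adjusted p = 0.000175). That rule counts a region of both lists without such a match once for each list. This lowers odds ratios by construction, so values below 1 under it do not show fewer overlaps than for independent lists. Of the 33, 23 had a higher top-peak similarity than any pair of different targets in the line, and 3, all with SMAD4 13.2.1A5, lay below the median of such pairs.

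The strongest sites of the 14 clones tried in more than one line were shared between lines to very different degrees. KLF10, a zinc finger protein induced by TGF-beta, was most alike, at 78.0% between HepG2 and MCF7, with 85.9% of the MCF7 peaks (Wilson interval 84.9 to 86.9%) inside the HepG2 list. For neither KLF10 list do the labels name a control of its own line. The zinc finger protein ZNF75A reached 72.4% between K562 and MCF7, DPF1, a subunit of BAF chromatin remodelling complexes, 62.0%, and NRF1 R157.1.3H1 60%. USF2 reached 44.8% between GM12878 and HepG2. ZSCAN2 reached 37.9%, NRF1 R157.1.3H3 33.4%, NRF1 R157.1.3D4 29.8%, the nuclear factor I protein NFIA 29.2% and ZNF18 23%. The ZMYM3 clone JH39.2.2F10 averaged 23.6% between HepG2 and K562, 19.4% between GM12878 and K562 and 13.5% between GM12878 and HepG2. ZMYM3 R259.2.2C3 reached 14.9% between HepG2 and MCF7, and the forkhead factor FOXO3 10.7% between HepG2 and K562.

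ZBTB2 had the lowest value, 5.2% between GM12878 and HepG2, yet its whole lists overlapped widely. Of its GM12878 peaks 69.6% (69.2 to 70.0%) were in the HepG2 list, and of its HepG2 peaks 75.6% (75.2 to 76.0%) were in the GM12878 list. Over the 29 pairs of one clone in different lines the mean similarity was 27.6% ± 18.7 (SD), against 1.68% ± 4.06 over 1675 pairs of different targets in different lines. The difference of 26.0 percentage points gave p = 2e-05, the smallest possible, in a two-sided permutation test. Pairs that share a library are not independent, and 16 of the 29 came from the 7 libraries of ZMYM3 JH39.2.2F10, with a mean of 18.8%. With 1 mean per clone the similarity was 37.1% ± 23.2 (SD over 14 clones). Without ZMYM3 JH39.2.2F10 the difference was 36.7 percentage points (permutation test, p = 2e-05). Of the 29 pairs, 28 lay at or above the 95th percentile of different-target pairs of the same lines, the exception being ZBTB2, and 6 lay above all of them.

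**Figure D3:**
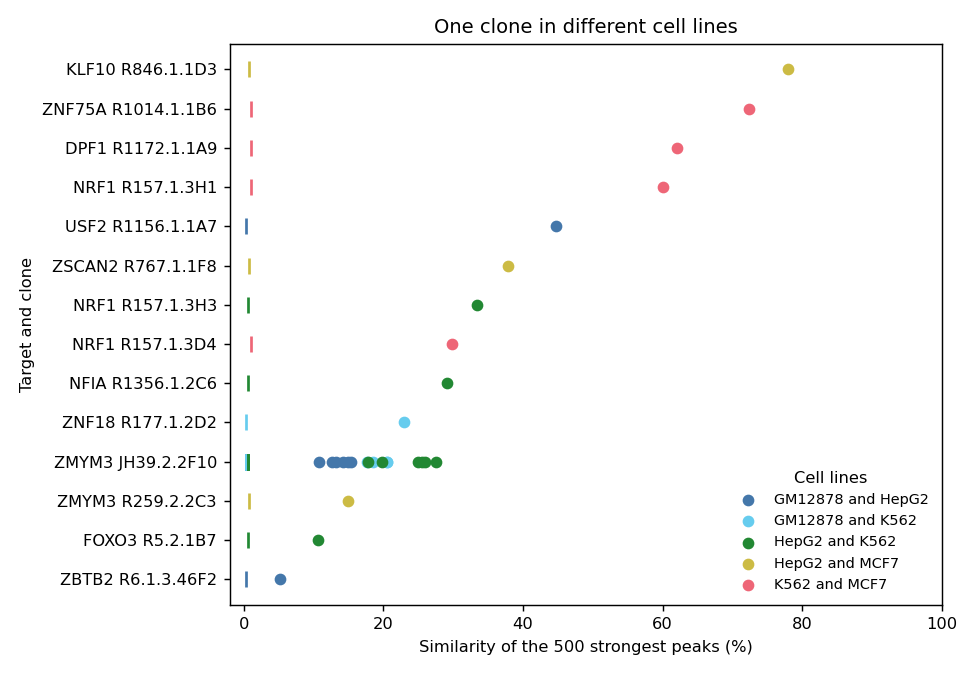
Each point is a pair of libraries of one clone from different cell lines, placed by the similarity of their 500 strongest peaks in percent (horizontal axis) and by target and clone (vertical axis), and coloured by the lines; short vertical marks are medians of different-target pairs of those lines. KLF10 is highest at 78.0% and ZBTB2 lowest at 5.2%.

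The share of regions found in every line varied in the same lists. ZBTB2 had 36054 of 63497 regions in both GM12878 and HepG2 (56.8%), and ZNF75A had 2176 of 4078 in both K562 and MCF7 (53.4%). NRF1 R157.1.3H1 had 3934 regions in both lines (41.4%), KLF10 3723 (32.6%) and USF2 11629 (25.6%). ZMYM3 JH39.2.2F10 had 2460 of 56642 regions in all 3 lines (4.34%), and 23102 regions in K562 only. FOXO3 had 250 of 6129 regions in both lines (4.08%). Common regions outside the recurrent set were ordered by mean rank of −log10 p, not by fold enrichment. The first in the 7 ZMYM3 JH39.2.2F10 libraries was chromosome 7, 2442290 to 2443031, with fold enrichments of 13.9 to 41.4. For KLF10 it was chromosome 17, 27278554 to 27279774 (58.7 and 110), for ZSCAN2 chromosome 11, 46638545 to 46639572 (117 and 123), for NRF1 R157.1.3D4 chromosome X, 17754845 to 17755510 (113 and 147), for USF2 chromosome 16, 1524347 to 1525545 (66.4 and 95.7), and for NFIA chromosome 11, 114030498 to 114031275 (39.5 and 52.3).

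The planned pairs of different targets had similarities from 0.2 to 30%. BATF and BATF3, related leucine zipper partners of AP-1 proteins in lymphocytes, shared 0.200% of their strongest peaks in GM12878. Of the 11434 BATF peaks 3.61% were in the BATF3 list. The overlap was lower than for lists drawn independently from the regions called in GM12878 (odds ratio 0.461, 95% interval 0.418 to 0.508, Fisher's exact test, adjusted p = 1.67e-67). This does not mean fewer overlaps than for lists placed at random on the genome. In the same line 80.8% of the BATF peaks were in the ZBTB2 list, so whether this BATF list represents BATF is open. HMG20A replicate 2 and the 2 ZMYM3 libraries in GM12878 shared 0.4 and 0.6%, with odds ratios of 0.990 (adjusted p = 0.866) and 0.917 (adjusted p = 0.00296) in Fisher's exact test. The 67-peak list of HMG20A replicate 1 had odds ratios of 13.9 and 4.65 with them, from 10 and 14 shared regions, and similarities of 30% and 3.83%, the first above the value between the 2 HMG20A libraries. Neither passed the threshold under reciprocal overlap (0.478 and 1.26), and the second did not without recurrent regions (1.29). RUVBL1, an ATPase of chromatin remodelling complexes, shared 1.2 to 4% with the 6 ZMYM3 libraries in HepG2, with odds ratios from 1.05 to 4.85. L3MBTL4 and TSC22D4 in HepG2 shared 16.2%, at the 92.1th percentile of different-target pairs, with an odds ratio of 12.6 (11.9 to 13.3). Of these 12 pairs, 8 overlapped more than independent lists, 2 less, and 2 did not pass the threshold. When an overlap of at least 50% of both peaks was required, 2 of the 12 overlapped more. Some odds ratios were then below 1, which does not show fewer overlaps, because that rule lowers them by construction. They were 0.234, 0.198 and 0.589 for RUVBL1 with ZMYM3 JH39.2.2B9 replicates 1 and 2 and JH39.2.2F10 replicate 1, and 0.169 for HMG20A replicate 2 with ZMYM3 replicate 1. Without recurrent regions the last pair was at 0.822, and RUVBL1 with JH39.2.2B9 replicate 1 at 0.733 (Fisher's exact test, adjusted p = 9.99e-06). Among peaks with a −log10 q of at least 5 that RUVBL1 pair was at 0.825 (Fisher's exact test, adjusted p = 0.0372). RUVBL1 with JH39.2.2B9 replicate 2, at 1.18 in the main test, did not pass the threshold there (0.998) or without recurrent regions (0.907).

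Some regions were called for most targets of a line. Recurrent regions numbered 822 of 125763 merged regions in GM12878 (0.654%), 1025 of 126424 in HepG2 (0.811%), 332 of 96575 in K562 (0.344%) and 895 of 38289 in MCF7 (2.34%). In all lines most regions belonged to 1 target, from 67.8% in MCF7 to 85.2% in K562. The 23 regions recurrent in all 4 lines included chromosome 21, 9825391 to 9827999, chromosome 6, 58776436 to 58779297, chromosome 17, 56708518 to 56709623, and 2 mitochondrial regions. In HepG2, chromosome 20, 43022964 to 43024398 was called for 16 of 17 targets. The share of the 500 strongest peaks in recurrent regions was highest for L3MBTL4 (58.6%), ATF2 (47.6%), FOXO3 (46.8%) and SMAD4 R516.1.1G12 (43.6%) in HepG2 and for STAT2 (43.0%) in GM12878, apart from HMG20A replicate 1. It was 0% for ZBTB2 in GM12878 and 0.6% for NRF1 R157.1.3D4 in K562.

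Control libraries were shared between antibodies, so different-target pairs with and without a shared control were compared. In GM12878 the mean similarity was 5.56% over 21 pairs with a shared control and 4.17% over 80 without (two-sided permutation test, p = 0.407). In K562 it was 1.34% over 14 pairs and 2.32% over 72 (permutation test, p = 0.425). In HepG2 it was 7.94% over 23 pairs and 5.22% over 214, a difference of 2.72 percentage points that was not past the threshold (permutation test, p = 0.081), but passed it when peaks were ranked by fold enrichment (3.42 points, permutation test, p = 0.00624). MCF7 had 1 control library, so no such comparison could be made.

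**Figure D4:**
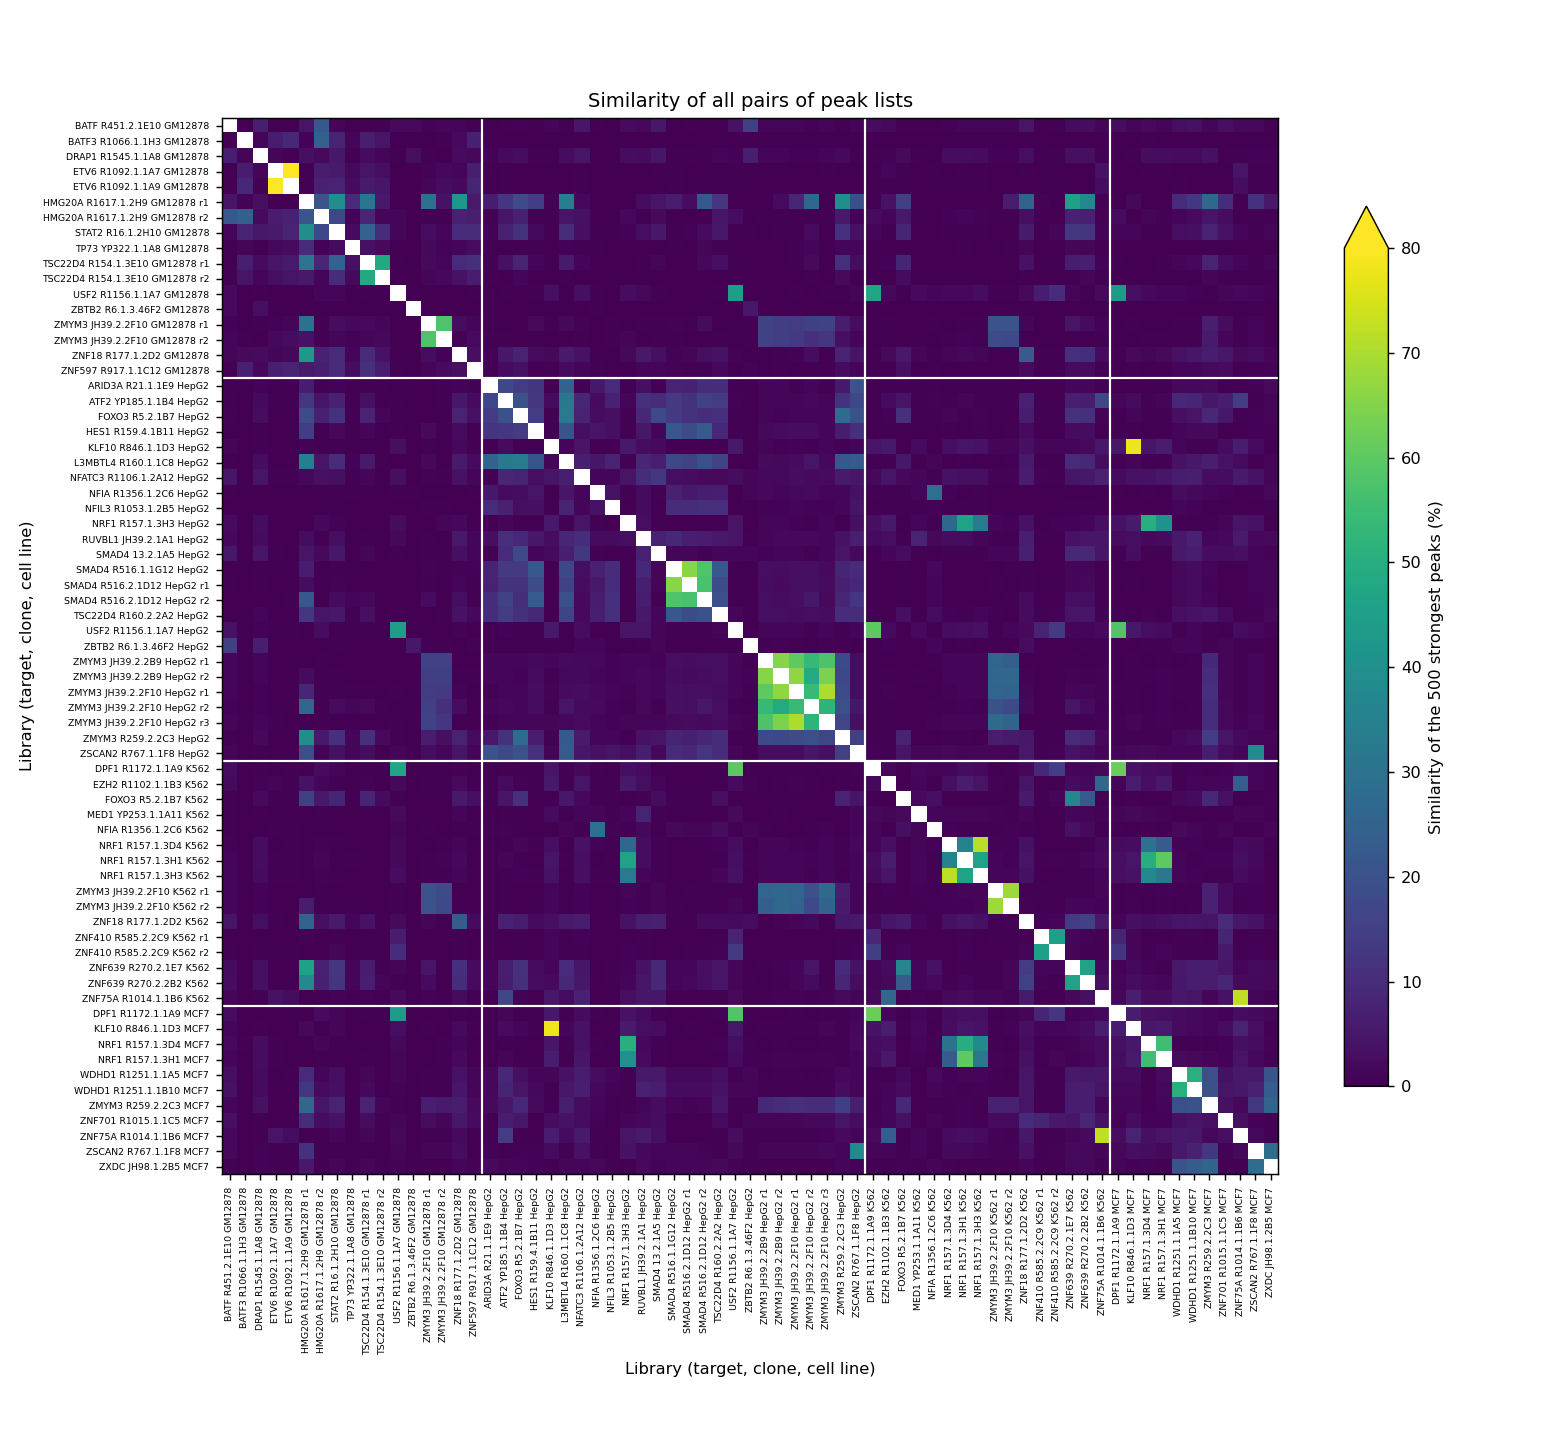
Each cell is a pair of libraries, coloured by the similarity of their 500 strongest peaks (scale in percent, values above 80 in the top colour), with libraries in the same order on both axes, white lines between GM12878, HepG2, K562 and MCF7 (from top left), r for replicate and an empty diagonal. The brightest blocks off the diagonal are libraries of one target, such as ETV6 in GM12878 at 81.9%, and DPF1 with USF2 at 43.5 to 59.8%.

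For some targets with 1 library in a line, the first-ranked regions outside the recurrent set are given here. They were not tested for being specific to the target. In GM12878 these were led by chromosome 19, 3721197 to 3721935 for DRAP1 (fold enrichment 113), chromosome 5, 111496306 to 111496797 for BATF (40.5), chromosome 5, 108497431 to 108498563 for BATF3 (55.1), chromosome 9, 139001446 to 139001900 for TP73 (59.0), chromosome 2, 191884848 to 191885438 for STAT2 (10.2) and chromosome 1, 236588429 to 236589010 for ZNF597 (45.5). In HepG2 they were led by chromosome 17, 61597543 to 61598434 for HES1 (47.1), chromosome 7, 45932940 to 45934345 for FOXO3 (13.3), chromosome 14, 37935297 to 37936279 for ARID3A (24.4), chromosome 19, 3397174 to 3399491 for NFIL3 (47.4), chromosome 5, 43066573 to 43067764 for ZSCAN2 (117) and chromosome 2, 91669903 to 91670752 for NFATC3 (10.6). In K562 EZH2, the catalytic subunit of Polycomb complex 2, was led by chromosome 13, 113343729 to 113344497 (129), and MED1, a Mediator subunit, by chromosome 17, 17875718 to 17876287 (69.4). In MCF7 ZXDC was led by chromosome 14, 91976382 to 91977100 (83.8) and ZNF701 by chromosome 1, 204661828 to 204662368 (45.5). No annotation of build hg19 was used here, so the genes at these positions are not named.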

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

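The rule that picked these values was chosen after the result was seen. Peak number moved in opposite directions between the same cell lines for different clones. From K562 to HepG2 the log2 ratio of mean peak number was 0.49 for FOXO3, with more peaks in HepG2, but -1.40 for ZMYM3 JH39.2.2F10, -1.50 for NFIA and -0.87 for NRF1 R157.1.3H3. From MCF7 to HepG2 it was 1.29 for KLF10 and 0.22 for ZMYM3 R259.2.2C3, but -0.37 for ZSCAN2. These differences were not tested, since all but ZMYM3 JH39.2.2F10 had 1 library per line. Some of these lists, such as those of KLF10, have no control of their own line named. Repeats of one clone in one line differed by up to 199 times in peak number.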

How the results depend on the processing

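The higher similarity of repeats of one clone, of clones against one target and of one clone in different lines kept its direction and stayed past the threshold in every alternative run, with p = 2e-05 in each permutation test. The differences ranged from 40.4 to 54.1, from 30.6 to 47.2 and from 20.0 to 36.7 percentage points. With single libraries left out they ranged from 47.6 to 53.6, from 35.5 to 44.0 and from 25.9 to 28.7. For the comparison across lines only the 17 libraries of groups with replicates were left out in turn. Libraries of groups without replicates, such as those of KLF10, were not, so the last range does not cover their influence. Alternatives without HMG20A, DPF1, ZMYM3 JH39.2.2F10 or mitochondrial peaks and with medians were added after the data were seen, as was leaving out libraries for the comparison across lines. The difference of log10 peak number between repeats and different targets was -0.041 and ranged from -0.244 (without HMG20A replicate 2, permutation test, p = 0.0555) to 0.0108 when single libraries were left out, never past the threshold, and 8 of these 17 values had the other sign. Without both HMG20A libraries it was -0.202 (permutation test, p = 0.0713).

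The shared-control difference in HepG2 passed the threshold with all peaks (8.49 points), with ranking by fold enrichment (3.42) and without recurrent regions (1.91); the cause was not tested. Recurrent regions were by construction more numerous when 25% of the targets sufficed, with 7261 in GM12878, 7177 in HepG2, 6252 in K562 and 5054 in MCF7, and fewer among peaks with a −log10 q of at least 5, with 387, 477, 175 and 518. Of the 12 pairs of different targets, 2 in place of 8 overlapped more than independent lists under reciprocal overlap, a stricter match by construction; of the 33 pairs of one target, 30 did. The pairs that lost the call there were both HMG20A libraries with each other and SMAD4 13.2.1A5 with R516.1.1G12 and with R516.2.1D12 replicate 2. The last of these went to an odds ratio of 0.436, but the reciprocal rule lowers odds ratios by construction. It also lost the call at a −log10 q of at least 5 (1.00) and without recurrent regions (0.899). RUVBL1 and HMG20A pairs with ZMYM3 that turned to an odds ratio below 1 past the threshold are given in the report. Of 288 similarities of single pairs or groups of pairs under an alternative, 153 moved by more than their spread or interval. No paired analysis was possible because the labels give no replicate numbers; the sign tests paired clones across lines, not replicates. Tests of transcription start distance, motifs and gene lists were not run. Unknown depth limits any comparison of peak numbers.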

Other observations

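The target pairs in this part, the tests of carry-over from the HepG2 ZBTB2 library alone and of another target behind the BATF and DRAP1 lists, the permutation test of chromosome 20 shares, and the grouping of HepG2 with MCF7 were chosen only after the results were seen. Outside the planned pairs, several targets shared strong sites, mostly in one line. FOXO3 reached 36.3% with ZNF639 R270.2.1E7 and 22.7% with R270.2.2B2 in K562, FOXO3 and L3MBTL4 32.8% in HepG2, and ZSCAN2 and ZXDC 28.7% in MCF7, the last pair with a shared control. Recurrent regions held 58.6% of the strongest peaks of L3MBTL4 and 46.8% of those of FOXO3 in HepG2. L3MBTL4 also reached 32.1% with ATF2 and 25% with ARID3A in that line. STAT2 in GM12878 reached 25.2% with TSC22D4 replicate 1, with which it shares a control, and 10.2% with replicate 2. Recurrent regions held 43% of the strongest STAT2 peaks and 40.8% of those of TSC22D4 replicate 1. The similarities of FOXO3 with L3MBTL4 and of STAT2 with TSC22D4 may therefore come in part from commonly called regions. BATF3 and HMG20A replicate 2 in GM12878, which also share a control, reached 24.6%, and 59.9% of all BATF3 peaks were in that HMG20A list. EZH2 in K562 reached 26.5% with ZNF75A in K562 and 24.0% with ZNF75A in MCF7. ZNF410 reached 8.8 and 14.8% (replicates 1 and 2) with DPF1 in K562 and 8 and 13.6% with USF2 in HepG2.

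The DPF1 lists resembled the USF2 lists more than any other pair of different targets in lists of at least 500 peaks, at 59.8 and 58.2% with USF2 in HepG2 and 47.0 and 43.5% with USF2 in GM12878, where USF2 itself reached 44.8% between those lines. Without recurrent regions the 4 pairs still averaged 48.5%, against at most 22.2% for any other pair of targets across lines, which argues against commonly called regions. Among DPF1 peaks that overlap USF2 and occur in 1 line only, own-line regions of other antibodies were favoured with an odds ratio of 60.8 (41.0 to 90.2, Fisher's exact test, p = 2.04e-145). The counts behind this odds ratio were 577 own-line and 67 other-line peaks of the 3372 in K562 only, and 337 and 47 of the 1171 in MCF7 only. For the peaks in these counts the odds ratio argues against reads carried over from the USF2 libraries of other lines. The remaining peaks of 1 line and those found in both DPF1 lists did not enter it, so carry-over stays open for them. Of the 2442 DPF1 K562 peaks also in the MCF7 list, 98.6% overlapped a USF2 list. DPF1 sitting at USF2 sites and a clone or library that captures USF2 cannot be told apart with that value, because both predict it. The labels give the DPF1 and USF2 libraries library numbers close to one another, and whether this bears on the overlap was not tested.

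BATF and DRAP1, a repressor subunit that binds the TATA-binding protein complex, had lists that lay mostly inside those of ZBTB2. In GM12878 80.8% of BATF and 76.9% of DRAP1 peaks were in the ZBTB2 list, against at most 27.3% for any list of at least 1000 peaks of another target, and without recurrent regions the shares were 82.2 and 78.3%, so neither the length of the ZBTB2 list nor commonly called regions alone give them. Each ZBTB2 list's 500 strongest peaks were in the BATF and DRAP1 lists more often than all its peaks, by 8.25 to 66.5 percentage points. Carry-over of reads from a ZBTB2 library predicts this. Binding of BATF and DRAP1 at ZBTB2 sites, or libraries of another target with such sites, can give it too, so it does not decide between them. Between the 500 strongest peaks of both lists, BATF reached 2 and 15% with ZBTB2 in GM12878 and HepG2, and DRAP1 3 and 6.6%. BATF reached 21.7% with HMG20A replicate 2, though 6.80% of all BATF peaks were in that list. ZBTB2 itself reached 5.2% between GM12878 and HepG2, so these similarities cannot decide on carry-over, which stays open. Carry-over from the HepG2 library alone stays open too, because the BATF list held 2.21% of the ZBTB2 peaks of GM12878 only and 0.746% of those of HepG2 only (ratio 2.96, 2.35 to 3.74), but 26% of the 500 strongest GM12878 peaks and 85.2% of the 500 strongest HepG2 peaks, where for DRAP1 these were 76.6 and 65.4%. GM12878 ZBTB2 peaks that overlap BATF or DRAP1 were in the HepG2 ZBTB2 list in 95.9% of cases, against 60% of the others, and from this value binding of BATF and DRAP1 at such sites and antibodies or libraries of another target cannot be told apart, because both predict it.

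Chromosome 20 held a mean of 5.12% of the peaks over the 21 groups of HepG2 and 3.41% over the 39 groups of the other lines. Without recurrent regions the difference was still 1.34 percentage points (two-sided permutation test, p = 0.00085), which argues against commonly called regions as the whole source. This comparison of groups ignored that 9 clones have groups on both sides. ZMYM3 had high shares in several groups, at 8.25% for JH39.2.2F10 and 6.79% for R259.2.2C3 in HepG2 and 9.65% for R259.2.2C3 in MCF7. The p-value of the permutation test may therefore be too small. Among the 9 clones tried in HepG2 and another line the share was higher in HepG2 for 7 (exact sign test, p = 0.18), so extra copies of chromosome 20 in HepG2, which predicted all 9, and the choice of targets cannot be told apart by these counts. KLF10 and ZMYM3 R259.2.2C3 had higher shares in MCF7, and after this was seen HepG2 and MCF7 were set together against GM12878 and K562, where all 10 clones were higher in HepG2 or MCF7 (exact sign test, p = 0.00195, ratios 1.22 to 1.84). That grouping came from the same values, so its p-value is too small, and control reads, which would show copy number, were not analysed here.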
